A study of Carassius auratus with 6 samples.

How the data were processed

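Liver RNA of crucian carp was sequenced in 6 libraries, 3 from control fish and 3 from fish held in low oxygen for 12 h. Per the labels, total RNA was extracted with Trizol from tissue frozen in liquid nitrogen. The labels give replicate numbers but do not state whether each replicate is a separate animal. The p-values of single genes therefore measure the spread between these samples. Reads were aligned with Bowtie2 2.2.8 and TopHat2 2.1.1, per the submitters' processing notes. The counter, the genome build, the annotation and the read filters are not given in the sources used here. Biochemical measurements, other time points, reoxygenation, small RNA and quantitative PCR belong to the same study and are not analysed here.

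The deposited table holds 47544 genes. Although its name says FPKM, the deposited signal of every gene in a library was a whole multiple of a single step, within 0.01 of a read, whatever the gene. The values therefore are read counts divided by a size factor per library, scaled by the authors and not divided by gene length. They are called normalized counts below. Whole reads were recovered from them, and the size factors lay between 0.8465 and 1.3079. The table also holds a log2 fold change, a p-value and an adjusted p-value per gene from the authors, whose test is not given in the sources used here.

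Of the identifiers, 46576 were NCBI gene identifiers and all of these matched the reference gene table of the goldfish assembly ASM336829v1, which was used for names and gene types only. Another 953 were new loci of the authors, and 15 were RNA identifiers. A gene name was present for 41199 genes. Among the copies named below, the reference lists hsp70 113046874, NFKBIA 113060950, cyp3a27 113091964 and fh 113055870 as pseudogenes. It does the same for CFB 113078028, Nop56 113063632 and NPM1 113075044. Per the file headers, the descriptions are those of the best matching protein of another species, so names such as sraP or Tf2-6 say which protein was closest and no more. Crucian carp and goldfish carry duplicated genomes, and each copy was tested as a gene of its own, given by name and identifier. How the counting treated reads shared by near-identical copies is not known, so levels of single copies are uncertain where copies are alike.

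Depth was 15734847, 17540766 and 16782876 recovered reads in control replicates 1 to 3, and 16939689, 17411676 and 22782649 in hypoxia replicates 1 to 3. Intervals and floors cover counting error only. A group at 0 reads in all 3 libraries was set to a floor of 3 reads over the group, with reads divided by the summed size factors of each group, so the fold is given as a lower bound. Where a group had 1 to 3 reads, the ratio is given with its exact 95% counting interval. Bounds and intervals are given for genes named by the rules below, not for those chosen after their values were seen.

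The test was limma's moderated test with a mean-variance trend (limma 3.58.1, R 4.3.3) on log2 of the normalized count plus 1, with no covariate and no replicate block. The 41045 genes with a mean of at least 1 over the 6 libraries were tested, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Adding 1 before the logarithm makes the fold of low genes smaller than the ratio of means. The design put the edgeR quasi-likelihood test in place of limma, with limma as the alternative, if the table held counts. It held counts divided by size factors, so limma was kept, although whole reads could be recovered. That choice was made after the table was seen, as was the use of edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads as alternatives.

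Apart from that choice between limma and edgeR, the comparison, the tests, the 28 gene lists, the 9 cell type marker lists and the rule for naming genes were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all 37 lists, with camera at an estimated correlation and fry as alternatives. Camera compares a list with all other tested genes. At the preset correlation its p-value does not measure how far the members of a list vary together between libraries. Fry asks whether the members of a list move, on balance, in 1 direction, and its mixed form whether they move in either direction. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone.

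Genes were named by these rules. The 10 largest rises and 10 largest falls were taken among genes with an adjusted p under 0.05, groups that did not overlap, a mean of at least 5 in the higher group and a name, with the copy of largest change standing for each product. From each list up to 4 members with the smallest p that rose or fell were named, or the 2 with the smallest p where none did. The genes hif1a, epas1, egln3, vegfa, igfbp1, epo, ldha, slc2a1, pdk1, ddit4, hmox1 and hsp70 were always given, and the 2 most abundant markers of each cell type. Anything outside these rules is said to have been chosen after its values were seen. These are the mitochondrially encoded transcripts, further members of lists with few changes, products with several risen copies and genes that part single libraries.

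The procedure was tested on simulated counts drawn from the means and depths of these libraries, with 200 of 40591 genes changed, each with a mean of at least 20. It found 1 of 75 genes changed 2-fold, 28 of 65 changed 4-fold and 52 of 60 changed 16-fold, with 9 false calls among 40391 other genes. Set against the genes found, these 9 were a larger share of all calls than the threshold for adjusted p allows on average. The share of false calls among the genes called in the real libraries was not measured. The list with raised genes was found, and 0 of 35 lists without raised genes were called. The simulated genes varied independently of each other, whereas estimated correlations within the real lists reached 0.60. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists here.

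Alternatives were a pseudocount of 0.1, no filter, filters at means of 5 and 10, quantile normalization, median-of-ratios scaling, equal totals, no trend, array weights, a replicate block, a minimum change of 1 on the log2 scale, leaving out each library, and control replicate 2 as the lone control. The filter at 10 and the lone control were added after seeing the data. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.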

Results

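RNA of crucian carp liver was measured in 3 control libraries and 3 libraries taken after 12 h of hypoxia, and the comparison asks which transcripts change when the fish is short of oxygen. Recovered reads per library lay between 15734847 and 22782649. Between 38944 and 41667 of the 47544 genes had at least 1 read. All levels are normalized counts, given as mean ± SD with n = 3 per group, and all changes are hypoxia minus control on the log2 scale, ± SE, with limma's moderated test and Benjamini-Hochberg adjustment.

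Heat shock genes, an oxygen sensor and an mTOR inhibitor were among the largest rises. The heat shock gene hsp70 113047258 went from 1.49 ± 1.78 to 22662 ± 14393 (log2 change 13.18 ± 0.62, adjusted p = 2.1e-05), and 6 other copies of it met the same conditions. The small heat shock gene hsp30 113057413 rose by 9.96 ± 0.71 with 3 more copies. The haem-binding plasma protein hemopexin (hpx 113108520) rose from 30.3 ± 48.8 to 3358 ± 993, a change of 8.48 ± 1.14. Its controls were at 3.3, 86.7 and 1, and against control replicate 2 alone the change was 5.21. Without hypoxia replicate 1 its call was lost (adjusted p = 0.056). The oxygen sensor Egln1 113117678, a prolyl hydroxylase that marks HIF-1α for degradation, rose from 43.8 ± 13.2 to 7745 ± 1539, a change of 7.45 ± 0.28 (adjusted p = 7e-06). The mTOR inhibitor ddit4 113111437 rose by 7.55 ± 0.53 and the kinase phosphatase DUSP8 113086109 by 7.58 ± 0.45. The glycogen-targeting subunit PPP1R3D 113045867 had 3 control reads, and its mean was 654 times the control mean (exact 95% counting interval 224 to 3175). The remaining large rises were the ubiquitin ligase rnf182 113105617 (7.54 ± 0.42), the mitochondrial carrier slc25a25a 113052745 (7.49 ± 0.42) and zgc:73324 113046942 (7.43 ± 0.66, or 5.73 against control replicate 2 alone).

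The largest fall was that of the peptide hormone gene kiss1 113055218, from 45.2 ± 11.9 to 0 in each hypoxia library, which was at least 50.8-fold lower (adjusted p = 0.0017). The translation initiation factor copy eif3g 113072795 changed by -5.14 ± 1.07, the interferon-induced membrane protein IFITM5 113043739 by -4.88 ± 0.56 and the retinol-binding protein RBP2 113098389 by -4.64 ± 0.78. The controls of eif3g were at 249, 19.7 and 360, and against control replicate 2 alone the change was -2.56 for eif3g and -3.46 for RBP2. The appetite peptide CARTPT 113040663 had 2 reads after hypoxia against 92 in controls, a ratio of 56.1 (exact 95% counting interval 15.1 to 470). CCDC152 113038933 had 3 reads after hypoxia against 93, a ratio of 37.8 (exact 95% counting interval 12.5 to 187). The other large falls were a transposon-like gene, Tf2-6 at a locus without an NCBI identifier (-4.18 ± 0.36), ociad1 113037937 (-4.05 ± 0.75), irak1bp1 113077672 (-4.03 ± 0.55) and sraP 113047623 (-4.02 ± 0.77). Of these falls, eif3g, RBP2, CARTPT, ociad1, sraP and CCDC152 lost their call without at least 1 of the libraries other than control replicate 2, with highest adjusted p of 0.19, 0.089, 0.077, 0.1, 0.12 and 0.093.

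**Figure D1:**
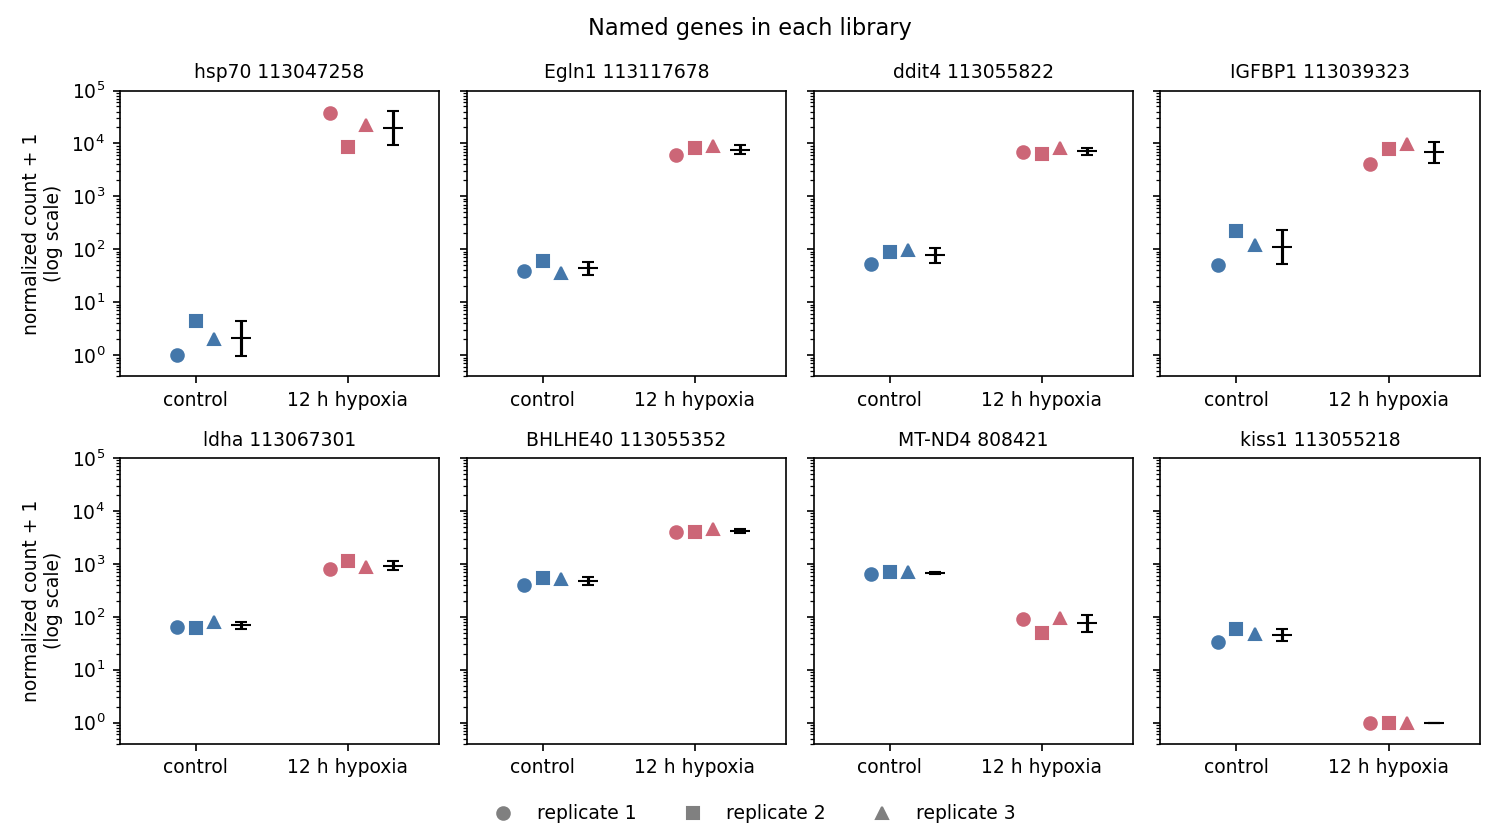
Normalized count plus 1 on a log scale in each of 6 libraries for 8 named genes, with the mean and SD of the log values of each group in black. The heat shock gene hsp70 113047258 lay between 0 and 3.47 normalized counts in controls and between 8705 and 37454 after hypoxia, and kiss1 113055218 was at 0 in all 3 hypoxia libraries.

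Counted over all genes, 750 rose and 171 fell out of 41045 tested, so 81.4% of the 921 changes were rises. The median change was 2.66 among rises and -2.25 among falls, and the smallest change called was 1.07. All 921 had groups that did not overlap, as did 10108 of all tested genes (24.6%, against 10% by chance). Against control replicate 2, the library farthest from its group, the median change was 2.60 for rises and -1.89 for falls. The count depended on the libraries. Without control replicate 2 it was 2363 (1423 higher, 940 lower). Without control replicates 1 and 3 it was 503 and 444, and without hypoxia replicates 1, 2 and 3 it was 293, 388 and 341. Under quantile normalization the falls increased to 274 and the rises made up 72.2%. The authors' own table listed 2609 genes with an adjusted p under 0.05, of which 1629 were higher, and it contained 920 of the 921 genes, all 920 with the same sign.

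Oxygen sensing and the targets of hypoxia-inducible factor (HIF) rose as groups. Of 42 HIF oxygen sensing genes 13 rose and 0 fell (20 and 0 adjusted over the list alone). They included 3 copies of cited2, which competes with HIF for its coactivator, at 6.12 ± 0.41 (113120722), 4.83 ± 0.38 (113063110) and 3.97 ± 0.37 (113062780). The egln1 product rose in 6 of 7 copies, by 1.97 to 7.45, of which 2 kept their call in every fit that left out 1 library (adjusted p up to 0.15 for the others). The gene egln3 113060960 rose from 36.4 ± 46 to 1032 ± 187 (5.66 ± 0.81). Of 9 copies of hif1a only HIF1A 113115010 rose, from 291 ± 45.9 to 1035 ± 311 (1.79 ± 0.28, adjusted p = 0.014), and the copies spanned -0.40 to 1.79. The 5 copies of epas1, which encodes HIF-2α, spanned -0.25 to 0.86 with 0 called and a lowest adjusted p of 0.2. Of 95 HIF targets 31 rose and 0 fell (42 and 3 adjusted over the list alone). All 4 copies of ddit4 rose, by 6.54 to 7.55, and together they went from 90.9 ± 26.4 to 9588 ± 701. All 5 copies of igfbp1, whose product holds insulin-like growth factors in the blood, rose by 2.31 to 5.94, and together went from 581 ± 348 to 16560 ± 6544. The lipase inhibitor Angptl4 rose in 4 copies, led by 113116506 (5.68 ± 0.31) and 113117239 (5.56 ± 0.35). Of 8 vegfa copies, vegfaa 113116535 rose by 2.76 ± 0.37, of 3 epo copies 113105893 rose by 2.50 ± 0.51, and of 4 slc2a1 copies 113050296 rose by 2.34 ± 0.34. The remaining copies of these 3 genes spanned -1.14 to 2.08 and were not called. PDK1 113053526 was at 75.5 ± 12.8 and 65.5 ± 19.4, a change of -0.23 ± 0.34 (adjusted p = 0.75). List medians were 0.77 for oxygen sensing and 1.1 for HIF targets, with camera adjusted p of 6.7e-14 and 2.3e-15. These were the only 2 of 37 lists called with an estimated correlation, with adjusted p of 0.029 and 0.031. With 1 library left out, HIF1A, egln3, vegfaa, epo and slc2a1 lost their call in 1 to 5 of 6 fits, with highest adjusted p of 0.079, 0.067, 0.053, 0.17 and 0.077. Of the called members, 5 of 13 in oxygen sensing and 18 of 31 among HIF targets kept their call in every such fit, among them all 4 ddit4, 4 of 5 igfbp1 and 3 of 4 Angptl4 copies, with adjusted p up to 0.083 for igfbp1 and 0.087 for Angptl4.

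Glycolysis genes rose in part, those of gluconeogenesis and glycogen changed in both directions, and single genes of mitochondrial pyruvate use and respiration fell. Of 77 glycolysis genes 15 rose and 0 fell (28 and 3 adjusted over the list alone). Lactate dehydrogenase ldha 113067301 rose from 68.4 ± 10.2 to 940 ± 174 (3.76 ± 0.25, adjusted p = 0.00016), whereas the more abundant copy 113043598, at 1208 ± 902 and 3575 ± 403, was not called (1.88 ± 0.53, adjusted p = 0.12). The lactate exporter SLC16A3 113070980 rose by 6.69 ± 0.52, phosphofructokinase PFKP 113042198 by 3.87 ± 0.33 and enolase ENO1 113068400 by 2.97 ± 0.35. Of the 15 risen genes 7 kept their call without each library in turn, with adjusted p up to 0.19 for the others. The median over the list was 0.76 (camera adjusted p = 1e-08, adjusted p = 0.085 with an estimated correlation). Of 54 genes of gluconeogenesis and glycogen 7 rose and 2 fell (11 and 7 adjusted over the list alone). Phosphoenolpyruvate carboxykinase, PCK1 113081964, rose from 33.4 ± 22 to 3585 ± 2810 (6.73 ± 0.69), PCK1 113050105 rose by 6.48 ± 0.69 and glucose-6-phosphatase G6PC 113111951 by 1.94 ± 0.28 (adjusted p up to 0.063 without control replicate 3 or hypoxia replicate 3). The glycogen-targeting subunit ppp1r3b 113064214 fell by 1.89 ± 0.32 on the log2 scale, as did glycogen phosphorylase Pygl 113056806, chosen after its values were seen (-2.89 ± 0.61, adjusted p up to 0.2 in fits that left out 1 library). Also chosen so, the glycogen synthase copies GYS1 113046917 and GYS1 113043441 rose by 1.29 ± 0.24 and 1.36 ± 0.28, and ppp1r3cb 113054142 by 2.30 ± 0.46. Each of these kept its call in 1 fit that left out 1 library. The gluconeogenesis and glycogen list had a median of -0.02, a mean of 0.34 and an upward test direction (camera adjusted p = 0.59, 0.86 with an estimated correlation).

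Among 39 genes of pyruvate dehydrogenase and ethanol 1 rose and 2 fell (7 and 5 adjusted over the list alone). The pyruvate carriers Mpc1 113057350 and Mpc2 113110000, which bring pyruvate into mitochondria, changed by -2.58 ± 0.36 and -2.19 ± 0.36, and the kinase Pdk2 113119818 rose by 2.76 ± 0.58. Members of this list had a median of -0.29 (camera adjusted p = 0.29, 0.82 with an estimated correlation). Of 46 members of the TCA cycle list 0 rose and 0 fell, over all genes and adjusted over the list alone. The smallest p belonged to the pseudogene fh 113055870 (-1.28 ± 0.30, adjusted p = 0.066) and to sdhb 113040348 (-1.21 ± 0.32, adjusted p = 0.1). Over the list, the median was -0.37 (camera adjusted p = 0.00025, adjusted p = 0.76 with an estimated correlation). Of 190 members of oxidative phosphorylation, 6 fell and 0 rose (99 and 0 adjusted over the list alone), and 12 had a change above 0. Ndufc2 113115312 changed by -1.44 ± 0.28, Ndufb3 113053443 by -1.23 ± 0.25, USMG5 113043557 by -1.19 ± 0.24 and mt-atp6 808428 by -1.70 ± 0.30. The list median was -0.75 (camera adjusted p = 1.2e-25, adjusted p = 0.45 with an estimated correlation), and it deviated from its mean by 0.23, 0.45 and 0.44 in controls and -0.23, -0.75 and -0.14 after hypoxia. Each of these 4 calls, and those of ppp1r3b, Mpc2 and Pdk2, was lost in at least 4 of the 6 fits that left out 1 library, with highest adjusted p of 0.13, 0.16, 0.13, 0.13, 0.12, 0.083 and 0.19 in the order given.

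Transcripts encoded in the mitochondrial genome, grouped after their values were seen, were lower in 11 of 12 cases in every hypoxia library than in every control library, and 7 of 12 fell. Of the complex I subunits, MT-ND4 808421 went from 681 ± 27.6 to 77 ± 24.5 (-3.18 ± 0.29, adjusted p = 0.00097). MT-ND5 808419 changed by -3.14 ± 0.43, MT-ND6 808424 by -3.23 ± 0.44, MT-ND4L 808426 by -3.58 ± 0.65 and MT-ND2 808429 by -2.80 ± 0.50. Cytochrome b (mt-cyb 808423) changed by -1.79 ± 0.24. The cytochrome c oxidase transcripts mt-co1 808417, mt-co2 808422 and mt-co3 808427 were not called, at -1.13 ± 0.49, -0.86 ± 0.52 and -1.34 ± 0.31. MT-ND3 808425 was the exception, at 287, 1603 and 296 in controls and 332, 226 and 529 after hypoxia. Without 1 of the libraries, MT-ND2, MT-ND4L and MT-ND5 reached adjusted p of 0.12, 0.12 and 0.054. The median over the 12 was -1.75, against -0.75 over the 189 nuclear members of the oxidative phosphorylation list.

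Part of the heat shock protein list rose, and 0 genes of the unfolded protein response were called. Heat shock proteins rose in 16 of 68 cases and 0 fell (24 and 0 adjusted over the list alone), and 12 of the 16 kept their call without each library in turn (adjusted p up to 0.098 for the others). The 7 copies of hsp70 rose by 11.04 to 13.18, and together they went from 12.1 ± 6.29 to 77391 ± 46891. Copy 113046944 went from 4.37 ± 1.26 to 17808 ± 10082 (11.54 ± 0.43). Copy 113046874, a pseudogene in the reference, had 0 reads in all 3 controls and was at least 2024-fold higher. Copies 113047268 and 113044026 had 2 control reads each, with ratios of 13472 and 7422 and exact 95% counting intervals of 3729 to 111251 and 2054 to 61288. The median over the list was 1.06 (camera adjusted p = 2.3e-15, adjusted p = 0.18 with an estimated correlation). Of 75 members of the unfolded protein response 0 rose and 0 fell, also adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.39). The smallest p there belonged to Dnajb11 113108519 (-1.47 ± 0.52, adjusted p = 0.19) and to Calr at a locus without an NCBI identifier (1.91 ± 0.71, adjusted p = 0.2). Calr had 1 control read, with a ratio of 10.7 (exact 95% counting interval 1.6 to 453).

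Genes of stress signalling and cell survival rose in part. The ATF4 amino acid response had 48 members, of which 4 rose and 0 fell (8 and 1 adjusted over the list alone). The phosphatase subunit ppp1r15a 113106413, which restores translation after stress, rose by 5.84 ± 0.38, Atf3 by 5.67 ± 0.54 (113120734) and 2.55 ± 0.35 (113051050), and CEBPB 113107548 by 2.30 ± 0.33. Members of this list had a median of 0.24 (camera adjusted p = 0.039, adjusted p = 0.76 with an estimated correlation). Of 70 members of p53 and apoptosis 9 rose and 0 fell (12 and 0 adjusted over the list alone). All 9 were copies of the survival factor MCL1, at 3.59 ± 0.29 (113116103), 2.42 ± 0.23 (113059157) and 2.48 ± 0.24 (113077609), and of gadd45, led by GADD45A 113045640 at 4.01 ± 0.44, and 4 of the 9 kept their call without each library in turn (adjusted p up to 0.12 for the others). Over the list, the median was 0.39 (camera adjusted p = 0.00095, adjusted p = 0.47 with an estimated correlation), and without control replicate 2 its adjusted p was 0.17. Gabarapl1 113059959 alone of 57 autophagy genes rose (2.87 ± 0.42) and 0 fell (3 and 0 adjusted over the list alone). That list had a median of -0.22, a mean of 0.04 and a downward test direction (camera adjusted p = 0.37). Sqstm1 113113483 alone of 76 antioxidant defence genes rose (2.18 ± 0.36), with 3 and 2 members higher and lower adjusted over the list alone, and a median of -0.26 (camera adjusted p = 0.11). Haem oxygenase had 0 of 3 copies called, at 3.17 ± 0.80 for hmox 113046688 (adjusted p = 0.085) and 1.17 ± 0.42 for 113095140 (adjusted p = 0.19), both higher after hypoxia than in controls. Atf3 113051050, CEBPB, Gabarapl1 and Sqstm1 lost their call in 1 to 3 of the fits that left out 1 library, with highest adjusted p of 0.051, 0.054, 0.053 and 0.1, and the ATF4 list in 3 of them, with adjusted p up to 0.35.

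Members of the circadian clock and glucocorticoid response lists rose. Of 99 circadian clock genes 22 rose and 0 fell (34 and 0 adjusted over the list alone). BHLHE40 rose by 3.11 ± 0.24 (113055352) and 4.25 ± 0.39 (113110917), CIART 113062149 by 2.72 ± 0.25 and Nr1d2 113054971 by 4.70 ± 0.45. Risen copies belonged to 10 genes, among them 4 of per1, 5 of nr1d2 and 4 of nfil3. When 1 library was left out, 10 of the 22 copies, from 5 genes, kept their call in every fit, 0 of the nfil3 copies did, and adjusted p for the others reached 0.19. The 16 copies of bmal1, arntl2, clock and npas2, the activators of the clock, spanned -1.43 to 1.49 and 0 were called. The list median was 0.66 (camera adjusted p = 2.3e-14, adjusted p = 0.085 with an estimated correlation). Of 43 glucocorticoid response genes 13 rose and 0 fell (19 and 2 adjusted over the list alone). The phosphatase dusp1-a rose by 5.75 ± 0.45 (113113377) and 5.34 ± 0.44 (113113503), and the clock gene per1, which both lists hold, by 3.16 ± 0.32 (113051396) and 1.82 ± 0.21 (113054209). Of the 13 risen genes 5 kept their call in every fit that left out 1 library (adjusted p up to 0.16 for the others). The median over the list was 1.37 (camera adjusted p = 1.6e-12, adjusted p = 0.085 with an estimated correlation). Insulin, AMPK and mTOR signalling had 84 members, of which 6 rose and 0 fell (9 and 0 adjusted over the list alone). The insulin receptor INSR 113040224 rose by 2.47 ± 0.30, its substrate irs1-b 113044375 by 1.96 ± 0.23, and foxo1a by 1.59 ± 0.24 (113115319) and 1.74 ± 0.31 (113098257). Members of this list had a median of 0.13 (camera adjusted p = 0.14), and the foxo1a copies lost their call in 2 and 3 of the fits that left out 1 library, with adjusted p up to 0.075 and 0.14. Of the 6 risen genes 2 kept their call in all 6 fits (adjusted p up to 0.21 for the others).

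Among lipid genes, a coactivator of fat oxidation, a triglyceride enzyme and a brake on sterol synthesis rose, and an elongase fell. In the list of fatty acid oxidation and ketogenesis, the coactivator PPARGC1A 113106421 alone of 56 members rose (3.88 ± 0.47) and 0 fell (1 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.05). In the list of fatty acid synthesis, 1 of 53 members rose and 2 fell (1 and 3 adjusted over the list alone). The elongase elovl6 113113882 changed by -1.97 ± 0.31, GPAM 113069503 by -1.19 ± 0.25 and the triglyceride enzyme dgat2 113109920 by 2.80 ± 0.48, with a list median of -0.07 (camera adjusted p = 0.15). In the list of cholesterol synthesis, insig1 113106153, which holds back sterol synthesis, alone of 51 members rose (2.35 ± 0.29) and 0 fell (2 and 4 adjusted over the list alone). That list had a median of -0.32 (camera adjusted p = 0.0086, adjusted p = 0.76 with an estimated correlation), and without hypoxia replicate 2 its adjusted p was 0.7. Bile acid synthesis and xenobiotic metabolism had 72 members, of which 3 rose and 3 fell, also adjusted over the list alone. Nr0b2 113059414, a repressor of bile acid synthesis, rose by 2.47 ± 0.42, cyp3a27 113091964 by 1.31 ± 0.22 and AHR 113064794 by 1.30 ± 0.22. The detoxifying cyp2k6 113051596 changed by -3.01 ± 0.44, and the cyp3a27 copies 113083758 and 113083760, chosen after their values were seen, by -2.71 ± 0.50 and -3.73 ± 0.75. Over the list, the median was -0.14 (camera adjusted p = 0.15). Of the genes named in these lists, PPARGC1A and insig1 kept their call without each library in turn, and the others reached adjusted p between 0.053 and 0.16 without at least 1 library. GPAM lost its call whichever library was left out (lowest adjusted p 0.06). AHR and the cyp3a27 copies 113091964 and 113083760 kept theirs in 1 such fit each.

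Inhibitors of NF-κB were among the inflammatory genes that rose. The cytokine il1b and NF-κB subunits did as well, but lost their call in most fits that left out 1 library. Of 88 genes of inflammation and acute phase 12 rose and 0 fell (27 and 0 adjusted over the list alone). Of 8 copies of nfkbia 5 rose. The product holds NF-κB in the cytosol, and the copies named by the rule rose by 4.17 ± 0.40 (113060787), 3.66 ± 0.45 (113060950), 2.58 ± 0.38 (113121166) and 2.91 ± 0.43 (113117624), the last 2 with adjusted p up to 0.051 in a fit that left out 1 library. Chosen after their values were seen, il1b 113110507 rose from 0 in each control to 46.3 ± 61.4, il1b 113110504 from 0.385 ± 0.667 to 32.4 ± 35.5, REL 113112658 by 2.24 ± 0.40, RELB 113115191 from 214 ± 76.4 to 901 ± 508 and the protease MMP9 113093908 by 2.05 ± 0.34, with adjusted p up to 0.16, 0.14, 0.11, 0.15 and 0.09 in fits that left out 1 library. The calls of il1b 113110507 and RELB were lost whichever library was left out, and il1b 113110504 kept its call in 1 such fit. Of the 12 risen genes 3 kept their call in every such fit. The list median was 0.77 (camera adjusted p = 1.2e-08, adjusted p = 0.45 with an estimated correlation). It deviated from its mean by -0.21, -1.23 and -0.29 in control replicates 1 to 3, and the median of the macrophage and granulocyte markers by 0.43, -1.21 and -0.18, so both were lowest in control replicate 2. Those markers were also higher after hypoxia (camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation), with adjusted p up to 0.56 without control replicate 2 or hypoxia replicate 2. Of 89 members of complement and coagulation 0 rose and 0 fell, also adjusted over the list alone, with CFB 113078028 at -2.33 ± 0.50 (adjusted p = 0.051), Masp1 113058755 at -1.57 ± 0.36 (adjusted p = 0.065) and a median of -0.13 (camera adjusted p = 0.095). Of 32 iron and haem genes 3 rose and 0 fell (6 and 0 adjusted over the list alone), namely hpx 113108436, from 151 ± 217 to 17133 ± 5549 (8.02 ± 0.95, or 5.35 against control replicate 2 alone), hpx 113108520 and the haem synthesis enzyme alas1 113054922 (1.59 ± 0.32). The median over the list was 0.20 (camera adjusted p = 0.044, adjusted p = 0.45 with an estimated correlation). That list was called in 2 of the 6 fits that left out 1 library, with adjusted p up to 0.081 in the others, hpx 113108520 had an adjusted p of 0.056 without hypoxia replicate 1, and alas1 reached 0.17 without hypoxia replicate 2.

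Of 5 lists of protein turnover, growth and reproduction, the proteasome list alone held a called gene. In the proteasome list Psma4 113066671 alone fell (-1.59 ± 0.30) and 0 members rose, 30 and 0 adjusted over the list alone, and 8 members had a change above 0. Its median was -0.60 (camera adjusted p = 8.7e-16, adjusted p = 0.45 with an estimated correlation). Of 209 cytosolic ribosomal protein genes 0 rose and 0 fell, also adjusted over the list alone, with rps28 113117226 at -1.20 ± 0.27 (adjusted p = 0.058), RPL3 113047013 at 1.23 ± 0.31 (adjusted p = 0.083) and a median of -0.35 (camera adjusted p = 3.3e-07, adjusted p = 0.76 with an estimated correlation). Of 49 members of ribosome biogenesis 0 rose and 0 fell, also adjusted over the list alone, with Nop56 113063632 at 1.42 ± 0.36 (adjusted p = 0.085), NPM1 113075044 at 1.18 ± 0.33 (adjusted p = 0.11) and a median of 0.39 (camera adjusted p = 0.015, adjusted p = 0.76 with an estimated correlation). These Nop56 and NPM1 copies are pseudogenes in the reference. Of 75 members of cell cycle and DNA replication 0 rose and 0 fell, also adjusted over the list alone, with ccnd1 113051788 at -1.69 ± 0.36 (adjusted p = 0.051), ccnd1 113106505 at -1.25 ± 0.31 (adjusted p = 0.084) and a median of -0.30 (camera adjusted p = 0.12). Of 49 members of vitellogenesis and egg envelope 0 rose and 0 fell, also adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.39). The yolk precursor vtg1 113039917 was at 540 in control replicate 2 and at most 31 in the other 5 libraries (-4.44 ± 1.23, adjusted p = 0.11), and the oestrogen receptor esr1 113063161 was at 1.84 ± 0.62 (adjusted p = 0.17). Psma4 lost its call in 5 of the fits that left out 1 library, with adjusted p up to 0.15, and the ribosome biogenesis list in 3, with adjusted p up to 0.24.

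Markers of exocrine pancreas, which lies within the liver in carp, varied more among the controls than between the groups. The median of 31 exocrine pancreas markers deviated from its mean by 1.59, -4.64 and -0.80 in control replicates 1 to 3 and by 0.82, 1.93 and 0.63 in hypoxia replicates 1 to 3, on the log2 scale. Carboxypeptidase CPB1 113042243 was at 57.8 in control replicate 2 and between 3369 and 39055 elsewhere (3.51 ± 1.82, adjusted p = 0.34), and Amy2 113060560 was at 12625 ± 8245 and 13247 ± 4688. That list had a median of 2.31 and 0 members called (camera adjusted p = 0.052, 0.76 with an estimated correlation). Of 23 endocrine pancreas markers 0 were called, or 7 higher adjusted over the list alone, with ins 113077182 at 3.55 ± 1.03 (adjusted p = 0.13), gcg 113064761 at 2.72 ± 0.95 (adjusted p = 0.18) and a median of 2.2 (camera adjusted p = 9.9e-06, adjusted p = 0.47 with an estimated correlation). Of 44 endothelial markers 4 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 1.3e-06, adjusted p = 0.47 with an estimated correlation). Chosen after their values were seen, these were the vascular growth factor receptors kdr, at 2.01 ± 0.34 (113063322) and 2.01 ± 0.37 (113120988), and FLT1 113066260 (1.57 ± 0.33), and FLI1 113118700 (1.44 ± 0.30), with adjusted p up to 0.1, 0.13, 0.16 and 0.17 in fits that left out 1 library. Among those fits, the 4 calls were kept in 1, 2, 1 and 0, in the order given. The endothelial median deviated from its mean by 0.17, 1.06 and 0.10 in hypoxia replicates 1 to 3. In hypoxia replicate 2 the stellate and fibroblast, macrophage and granulocyte, and bile duct medians were also highest, at 1.52, 1.35 and 0.91, and the hepatocyte median was at -0.60, near that of control replicate 3 (-0.59). The abundant endothelial markers kdrl 113113945 and VWF 113079219 were at 0.62 ± 0.26 and 0.84 ± 0.53 and were not called.

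Hepatocyte markers went both ways. Of 29 members 2 rose and 3 fell, also adjusted over the list alone, with a median of -0.00, a mean of 0.22 and a downward test direction (camera adjusted p = 0.41). Both rises were hpx copies, and the falls, chosen after their values were seen, were the lipoprotein APOA1, at -2.27 ± 0.40 (113116733) and -2.47 ± 0.50 (113116736), and the fatty acid carrier fabp10a 113115755 (-2.46 ± 0.43), with adjusted p up to 0.12, 0.16 and 0.12 in fits that left out 1 library. Each of these 3 falls kept its call in 1 such fit. The 2 most abundant hepatocyte markers, the fibrinogen genes FGA 113044501 and FGB 113044503, were at 0.41 ± 1.52 and 0.21 ± 1.51. Of the macrophage and granulocyte markers 0 of 37 were called, with Cd74 at -0.72 ± 0.40 (113069553) and -0.57 ± 0.38 (at a locus without an NCBI identifier) and a median of 0.73 (camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation, and up to 0.56 without control replicate 2 or hypoxia replicate 2). Of 25 erythrocyte, 14 lymphocyte, 50 stellate and fibroblast and 35 bile duct markers 0 were called, also adjusted over each list alone, with camera adjusted p of 0.99, 0.83, 0.072 and 0.057. The erythrocyte list had a median of -0.03, a mean of 0.13 and an upward test direction, with hbb 113082649 at 1.25 ± 0.83 and hba 113082666 at -0.19 ± 0.91. The lymphocyte list had a median of 0.11, with IL7R at -0.77 ± 0.44 (113038619) and -0.24 ± 0.37 (113064274). The stellate list had a median of 0.40, with FN1 113044581 at 0.36 ± 0.63 and COL1A1 113119710 at -1.05 ± 0.34, and the bile duct list a median of 0.35, with krt18 113092494 at 0.13 ± 0.35 and ANXA4 113110305 at 0.08 ± 0.43.

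**Figure D2:**
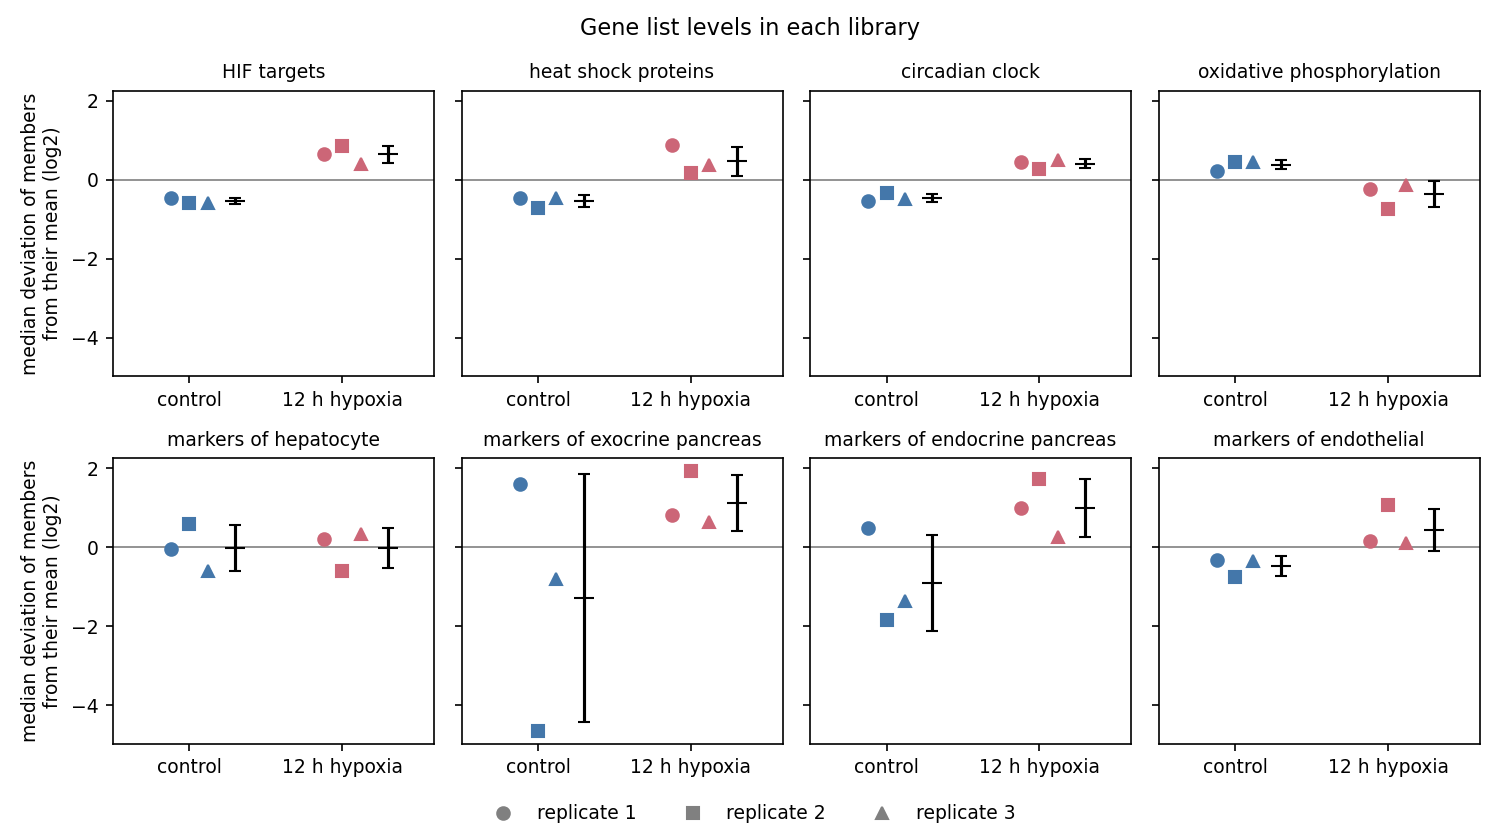
Median deviation of list members from their mean over all libraries, in log2 units, in each of 6 libraries for 8 lists, with the mean and SD of each group in black. The HIF targets lay between -0.59 and -0.45 in controls and between 0.41 and 0.85 after hypoxia, while the exocrine pancreas markers lay at -4.64 in control replicate 2.

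Across the 37 lists, camera with the preset correlation called 16 of 28 gene lists (11 higher, 5 lower) and 3 of 9 marker lists (all higher). An estimated correlation left 2 gene lists and 0 marker lists, fry called 6 and 0, and its mixed form 23 and 2. The 6 gene lists called by fry were HIF oxygen sensing and HIF targets (fry adjusted p = 0.00021 and 0.001) and 4 others. Those were glycolysis, heat shock proteins, circadian clock and glucocorticoid response (fry adjusted p of 0.0057, 0.0057, 0.005 and 0.0057). Oxidative phosphorylation, proteasome and inflammation were not called by fry (adjusted p of 0.077, 0.078 and 0.11). The same libraries were also split differently. In the 9 other splits of the 6 libraries into 3 and 3, camera with the preset correlation called between 13 and 30 lists against 19 for hypoxia, and 6 of the 9 called at least as many. The other 9 splits gave 0 genes each with limma, with at most 3591 genes at an unadjusted p under 0.05, against 921 genes and 7653 for hypoxia. Each of those splits holds both groups on both sides, so the treatment difference widens their spread and the 0 calls say little. The sides hold the groups in unequal numbers, so part of the treatment difference remains. Their list counts therefore do not show what camera calls without a treatment difference. The first principal component held 41.2% of the variance, and the second held 26.7% and set control replicate 2 apart. On the first, hypoxia libraries lay between 85.3 and 126.5 and control replicates 1 to 3 at -138.4, -14.5 and -159.2. Across genes, control replicate 2 had Pearson correlations of 0.903, 0.858 and 0.92 with hypoxia replicates 1 to 3. Those with control replicates 1 and 3 were 0.876 and 0.885, so it was closer to hypoxia replicates 1 and 3 than to its own group.

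**Figure D3:**
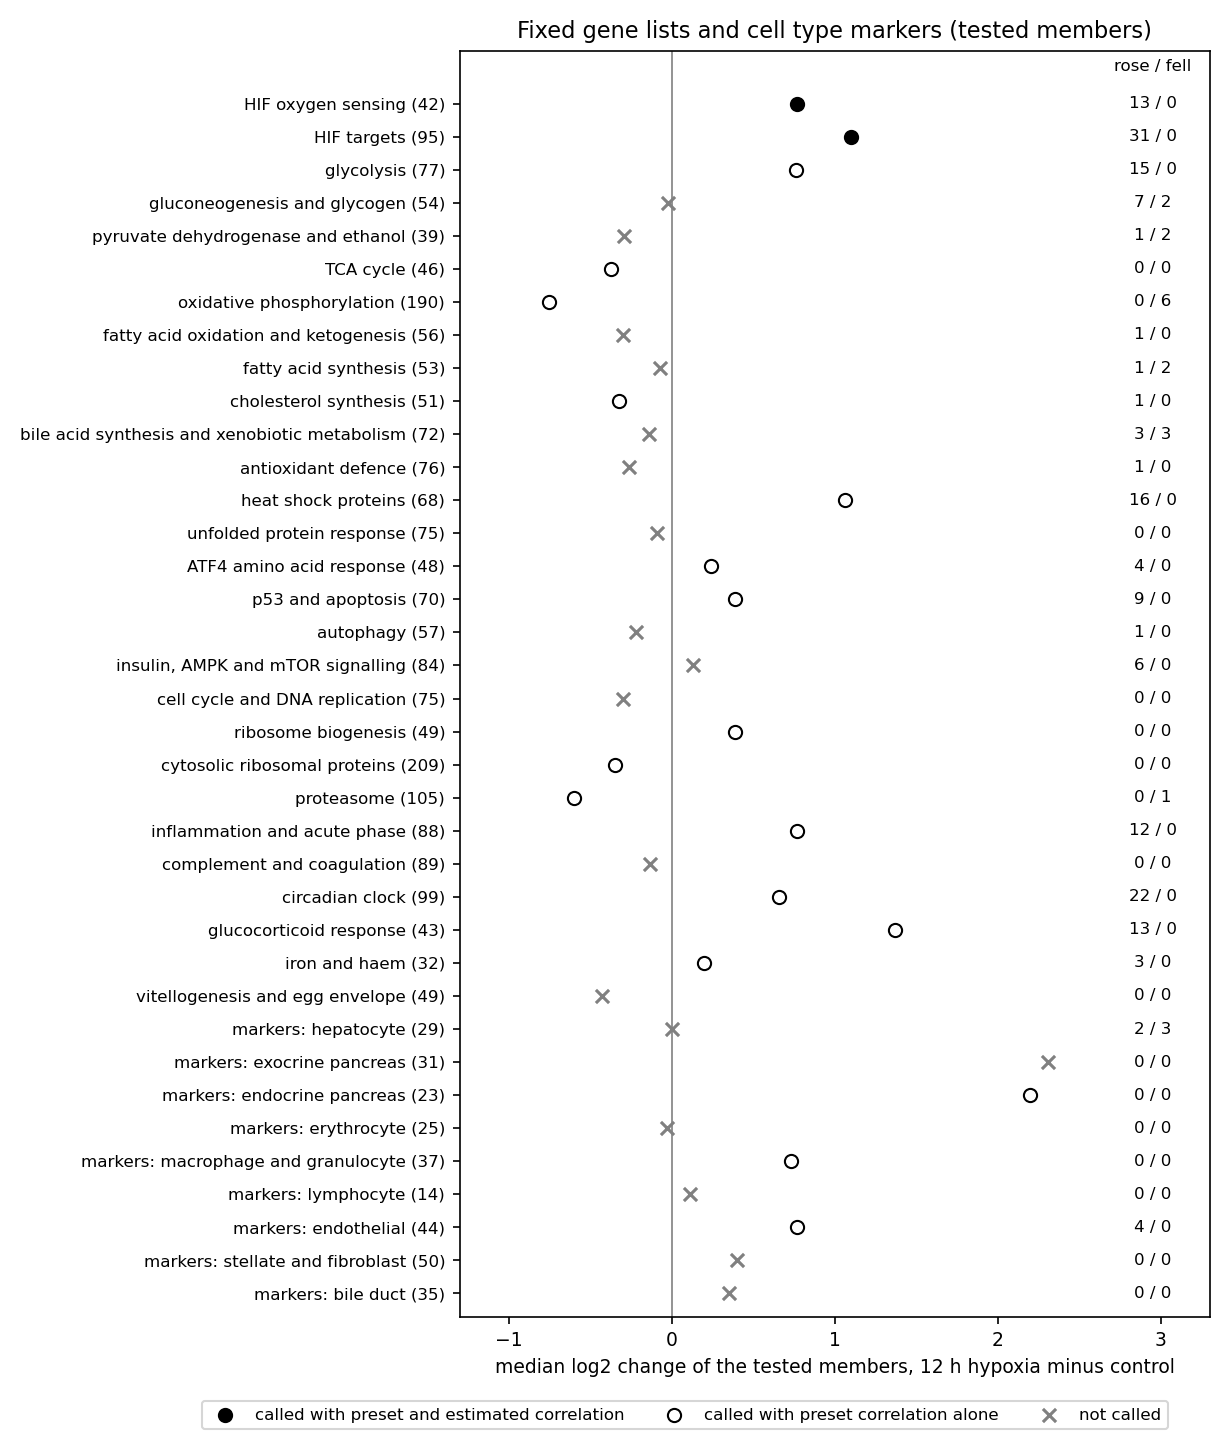
Median log2 change of the tested members of 37 fixed lists, hypoxia minus control, with the number of members in parentheses and the numbers that rose and fell at the right. Filled circles mark the 2 lists called with both correlations, open circles those called with the preset correlation alone, and crosses those not called, with HIF targets at 1.1 and oxidative phosphorylation at -0.75.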

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

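DESeq2, edgeR as an alternative to limma, the filter at a mean of 10 and control replicate 2 as the lone control were chosen after seeing the data. The count of 921 genes at 12 h of hypoxia stayed within 1.5 times under the pseudocount of 0.1 (723), no filter (917), filters at 5 (902) and 10 (907), quantile normalization (986), equal totals (757) and edgeR (845). Median-of-ratios scaling also gave 921. The size factors of the deposited values equalled the median-of-ratios factors, so this setting could change nothing and is no test. A minimum change of 1 removed no gene. No other scaling shifted the median of all genes by over 0.1 on the log2 scale.

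Some settings moved the counts. Without the trend 376 genes were called (321 higher, 55 lower) and with array weights 2482 (1560 higher, 922 lower), where control replicate 2 had a weight of 0.436. DESeq2 called 2633 (1640 higher, 993 lower), of which 917 were among the 921, and edgeR shared 786. Quantile normalization called 274 lower genes. The cause was not tested. Leaving out 1 library gave 293 to 2363 genes (262 to 1423 higher, 31 to 940 lower), with fewer samples in each fit. With control replicate 2 as the lone control, assumed to vary like the hypoxia group, limma called 0 genes (0 higher, 0 lower), with 5550 at an unadjusted p under 0.05, and edgeR called 178 (139 higher, 39 lower), of which 112 were among the 921.

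Same-numbered libraries did not deviate together, with correlations of -0.07, -0.19 and -0.03, against -0.19 to 0.21 for differently numbered ones. This shows no pairing by number, but with 3 libraries per group it cannot exclude one. A replicate block called 415 genes (354 higher, 61 lower), 398 of them among the 921, and 15 gene lists and 4 marker lists.

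For gene lists at 12 h of hypoxia, 16 with the preset correlation became 2 with an estimated correlation and 6 with fry, and for cell type marker lists 3 became 0 with either. The other settings gave 14 to 22 gene lists. Marker lists numbered 6 under quantile normalization and 6 with the lone control, and gene and marker lists 15 to 22 and 2 to 6 when 1 library was left out. The cause was not tested.

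Of 97 named genes called, 57 kept the call in each fit that left out 1 library, 55 kept it under all alternatives other than these, the lone control and the block, and 0 kept it under every alternative, since limma with the lone control called none. Among all 144 named genes the alternatives were the same side and direction 2384 times, weaker 389, stronger 65 and of opposite sign 29. Of the 2384, 144 came from median-of-ratios scaling, which the values already carried. No called gene changed sign.

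The sign changes were in genes that had not been called. With the lone control, limma and edgeR gave PDK1 113053526 0.05 and 0.11, FGB 113044503 -0.37 and -0.29, Amy2 113060560 -0.81 and -0.73, IL7R 113038619 0.31 and 0.32, FN1 113044581 -0.19 and -0.11, and ANXA4 113110305 -0.22 and -0.03, and limma gave hbb 113082649 -0.09. For hba 113082666, DESeq2 gave 0.27, edgeR 0.24 and array weights 0.63. Array weights also gave krt18 113092494 -0.02, ANXA4 113110305 -0.12 and MT-ND3 808425 0.10. Leaving out 1 library gave PDK1 -0.42 to 0.01, Amy2 -0.17 to 0.69, hba -1.16 to 0.78, IL7R 113064274 -0.63 to 0.09, krt18 -0.07 to 0.34, ANXA4 -0.42 to 0.34 and MT-ND3 -1.01 to 0.23.

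Lists that changed direction had not been called, and the adjusted p was as follows. Array weights gave 0.95 for the list of pyruvate dehydrogenase and ethanol, 0.77 for the list of unfolded protein response, 0.44 for the list of vitellogenesis and egg envelope, 0.53 for the list of markers of hepatocyte and 0.79 for the list of markers of lymphocyte. The lone control gave 0.33 for the list of gluconeogenesis and glycogen, 0.89 for the list of insulin, AMPK and mTOR signalling and 0.29 for the list of markers of erythrocyte. For the last, no trend gave 0.74, no filter 0.88, equal totals 0.96 and fry 0.92, and for lymphocyte markers no filter gave 0.88 and the filter at 10 gave 0.88. Leaving out 1 library gave 0.11 to 0.97 for gluconeogenesis and glycogen, 0.089 to 0.94 for pyruvate dehydrogenase and ethanol, 0.023 to 0.96 for the list of fatty acid synthesis, 0.024 to 0.77 for the unfolded protein response, 5.8e-05 to 0.65 for the list of cell cycle and DNA replication, 0.009 to 0.7 for the list of complement and coagulation and 0.024 to 0.96 for vitellogenesis. For markers it gave 0.052 to 0.7 for hepatocyte, 0.23 to 0.72 for erythrocyte, 0.11 to 0.96 for lymphocyte and 0.0014 to 0.72 for the list of markers of stellate and fibroblast. Of these opposite directions only that of vitellogenesis without control replicate 2 passed (0.043).

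In simulated counts 1 of 75 genes that changed 2-fold and had a mean of at least 20 was found, so small changes are not excluded by a missing call.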

Other observations

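All tests in this part were chosen only after the results were seen. Several products had more than 1 risen copy. All 7 copies of DUSP8 rose, by 2.33 to 7.58, all 7 of JUNB by 2.61 to 4.78, all 4 of JUND by 1.92 to 2.15 and 6 of 8 of BTG1, which restrains proliferation, by 1.33 to 3.13. Among kinases and phosphatases, 4 of 7 copies of SIK2 rose by 1.33 to 5.38 and 4 of 5 of PPTC7, a mitochondrial phosphatase, by 1.97 to 4.24. The cyclic AMP-responsive element modulator CREM rose in 4 of 7 copies, by 1.39 to 2.18, and the elongation factor ELL2 in 4 of 5, by 1.32 to 2.41. All 18 products with at least 4 called copies had rises and no falls among them. In every fit that left out 1 library, 4 of the 7 DUSP8, 5 of the 7 JUNB, 1 of the 4 JUND, 4 of the 6 BTG1, 3 of the 4 SIK2, 2 of the 4 PPTC7 and 0 of the 4 CREM and 4 ELL2 copies kept their call. Their highest adjusted p in these fits were 0.087, 0.068, 0.17, 0.14, 0.15, 0.11, 0.18 and 0.17.

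Some genes stood out in 1 or 2 libraries. The yolk precursor vtg1 113039916 was at 19099 in control replicate 2 and 1250 in hypoxia replicate 1, and at 8.01 to 22.9 in the other 4. The keratin krt8 113041112 was at 2664 in control replicate 3 and at most 75.7 elsewhere, and krt8 113092492 at 1424 and at most 21.4. With a level of at least 50 and a difference of at least 16-fold, 32 genes were low in control replicate 2 alone and 5 were high in it alone, 25 were high in control replicate 3 alone, and 7 were high in control replicate 2 and hypoxia replicate 1.

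A pattern of gene copies parted control replicates 1 and 3 from the other 4 libraries. By the same limits 52 genes were high in those 2 controls and 35 in the others, 87 in all, against at most 7 in any of the 14 other ways of parting 2 libraries from 4. Of the 87, only hpx 113108520 was called at 12 h of hypoxia. RPL38 113104119 was at 1273, 6.94 and 1219 in controls and at most 2.36 after hypoxia, while rpl24 113044665 was at 22, 3723 and 55.1 in controls and 2125 to 2428 after hypoxia. These genes were chosen for crossing the treatment, so hypoxia as their cause was not tested. A strain or donor variant against the reference, which would move reads between copies, and RNA of a cell type without a marker list cannot be told apart for these genes. For the 9 ribosomal proteins concerned, the sum over copies differed by a median of 1.70-fold between highest and lowest library. The split copy made up a median of 13.8% of its sum where it was highest, so most sums would stay near level even if no reads moved. The exception was rpl24, whose split copy made up 48.5%: its sum was 6937, 7673 and 7038 in controls and 4733 to 5583 after hypoxia, so its other copies were lower where the split copy was high. The COX14 homolog si:dkey-222f2.8 had 2 split copies that went opposite ways. Copy 113100955 was at 478, 0 and 476 in controls and at most 1.63 after hypoxia. Copy 113080557 was at 0, 525 and 7.01 in controls and at 310, 204 and 270 after hypoxia. Reads moving between copies would give such values for these proteins, but single proteins do not decide for the 87 genes. In the marker lists were 2.3% of the 87 genes, but these lists hold only 0.7% of all tested genes, so this share cannot decide either. None of the 9 marker medians parted control replicates 1 and 3 from the other 4 libraries. For exocrine pancreas they were 1.59 and -0.80 in those controls and -4.64 to 1.93 elsewhere. For hepatocyte they were -0.05 and -0.59 in those controls and -0.60 to 0.59 elsewhere. This argues against RNA of these 9 cell types as the source.

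The rise of clock genes may come from hypoxia, which the design names, or from a difference in the time of day at sampling, which the labels do not give. Reads shared between the copies of a single gene would not spread a rise over 10 genes of the list, to which the 22 risen copies belonged. How many copies of each gene rose on their own cannot be told from this. The copies of bmal1, arntl2, clock and npas2, which peak in the opposite phase, had a median change of 0.09 with members from -1.43 to 1.49. Sampling at another phase and hypoxia cannot be told apart for these genes, because each group was seen at a single time and the members went both ways.

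The lower level of mitochondrially encoded transcripts may reflect hypoxia. Under the other scaling nearest to 0 the median change of the 12 transcripts was -1.66. This cannot decide on the authors' scaling as the cause. Quantile normalization and equal totals shifted genes by a median of only -0.079 and 0.084, and median-of-ratios scaling was no test. A variant that parts the controls is argued against, since the median against control replicate 2 alone was -1.89. A uniform loss of mitochondrial RNA is argued against by the ratio of 6 complex I to 3 cytochrome c oxidase subunits within a library, which was -6.62 ± 0.07 in controls and -8.26 ± 0.52 after hypoxia on the log2 scale (SD, n = 3), a change of -1.64 ± 0.30 (SE). Differences in the stability or the selection of these transcripts were not tested.

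The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 921 genes and was the only 1 of 10 to give as many, and the highest of the others gave 0. The other splits hold both groups on both sides, which widens the spread within a side, so their 0 calls say little. The real split gave 19 lists, and 7 of the 10 splits gave at least as many, the highest of the others giving 30. Part of the treatment difference remains in the other splits, so their list counts do not show what camera calls without it. The 3591 genes at an unadjusted p under 0.05 in the highest other split came from setting control replicate 2 beside hypoxia replicates 1 and 3.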
